A study of Arabidopsis thaliana with 4 samples.

How the data were processed

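Whole Arabidopsis thaliana plants, 10 days old, of the Wassilewskija accession (ecotype Ws-2, called WS here) and of a line labelled gpa1 were compared with and without abscisic acid (ABA). Per the labels, the treated plants received 100 µM ABA for 3 h, and 10 plants were pooled for an RNA sample. The plants grew on agar with Murashige and Skoog medium at 21 °C in cycles of 16 h light and 8 h dark. Per the labels' protocols, total RNA was extracted with Trizol and a Qiagen kit, converted with an oligo(dT) primer to biotin-labelled cRNA, and hybridised to Affymetrix ATH1 arrays. There were 4 arrays, 1 for each combination of genotype and treatment. No group had a replicate, and the number of arrays limits the precision of every value.

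The deposited values are linear probe-set intensities of 22810 probe sets per array. The 2%-trimmed mean of each array was 100.0, so the authors' values had been scaled to a common level before deposit. The program that summarised the probes into these intensities is not given in the sources used here, and detection calls were not used here. The 64 control probe sets were set aside for array checks, and 22746 probe sets were analysed. Each array was scaled to the same 2%-trimmed mean, where the deposited trimmed means already lay at 100.0. Values below the 30th percentile over all arrays, an intensity of 19.2, were raised to that floor, and log2 was taken. A value at the floor is only an upper bound, so a fold against it is written as "at least". Probe sets above the 40th percentile of mean log2 intensity were tested, 13647 in all.

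Probe sets were named through the platform's gene annotation, updated by gene identifier through the RefSeq annotation of assembly TAIR10.1. That table gave 1 gene for 13513 probe sets and several genes for 503, and it did not list 8730, which are unnamed here. Of the tested probe sets, 7285 had 1 gene. The probe set of GPA1 is among those unnamed here, so GPA1 was not analysed here. Gene order along the chromosomes came from the start coordinates in the same RefSeq annotation, and distances were counted in tested genes. Upper bounds of random placements along the chromosomes are their 97.5th percentile.

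The averaged ABA response and the averaged genotype difference were tested with limma 3.58.1 in R 4.3.3. The model held treatment and genotype without an interaction, which leaves 1 residual degree of freedom per probe set. The variance was moderated with a trend on intensity (eBayes), tests were two-sided, and p-values were adjusted by Benjamini-Hochberg at 0.05. In this design the 2 genotypes stand in for replicates of the treatment, and the 2 treatments for replicates of the genotype. The spread comes only from how far the 2 estimates of each effect lay apart over single pools of plants, and it is pooled over probe sets. The pooled spread carried a median of 171 prior degrees of freedom against 1 of the probe set itself, so a probe set whose own 2 estimates lay far apart can still pass. The 4 comparisons of 1 array with another, and the difference between the 2 ABA responses, have no replicate check and no p-value. They were counted at a 2-fold change, and the difference of the 2 responses was also halved so that it has the same error as the averaged contrasts. The gpa1 response was set against the WS response by the slope of the principal axis. Pearson correlations across probe sets are descriptions, since probe sets are not independent replicates.

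Before the data were examined, 27 gene lists with 425 genes were fixed from textbook knowledge. Of these genes, 49 had a named probe set, 8 were dropped because the annotation did not give their locus the listed name, and 32 of the remaining 41 were tested. For lists with at least 3 tested genes, the median log2 change was placed among 10000 random lists of the same size matched on mean expression in 20 bins. In addition, 34 gene families were defined by gene name after the annotation had been seen and before any gene's value was looked at. The 33 families with enough tested genes were tested for an excess of higher or lower calls with a one-sided Fisher's exact test, adjusted over 66 tests, against all 7211 tested genes.

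The genes named in the text were chosen by a rule fixed beforehand. First came GPA1 and AT3G26300, the locus that the labels give for the insertion. For each of the averaged contrasts and the difference of the responses, the 10 highest and the 10 lowest tested probe sets with 1 gene and intensities above the floor on all arrays were taken, with an adjusted p under 0.05 for the averaged contrasts. Where fewer than 10 passed, probe sets changed at least 2-fold in both single comparisons would have been used. List members followed, up to 4 per list with the largest absolute change, with any whose single comparisons went opposite ways by over 2-fold each. Last came the 5 per direction with the largest bound among those at the floor on 1 side in both single comparisons. The remaining list members, and the probe sets of no list that the rule leaves out, are named only where stated, after their values were seen. A gene with several probe sets took the mean of their log2 values in the lists and families.

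The limma step was tested on simulated arrays of 13647 probe sets with 200 changed by known amounts with ABA, alike in both genotypes. This is a far smaller share than was called in the data. No genotype difference was simulated, so its recovery was not tested. For the averaged ABA response with equal spread, 92% of changes of 1 on the log2 scale and 100% of changes of 2 were recovered, with 15 false calls. With a spread that varied between probe sets, 63% and 99% were recovered, with 26 false calls. The list percentiles were tested on simulated sets of 10 genes shifted by 1 on the log2 scale, of which 16 of 20 lay above the 97.5th percentile. The simulated genes were independent, and the fixed lists given a percentile had only 3 to 5 tested genes. This recovery therefore need not hold for those lists.

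Alternatives covered quantile normalization, median centring, the values as deposited, floors at the 15th and 45th percentiles, no filter, a filter at the 60th percentile, limma without trend or with robust moderation, each factor fitted alone, each array left out, the brightest probe set of a gene, unmatched random lists, and other slopes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.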

Results

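Transcript levels were measured on 4 arrays of whole 10-day-old Arabidopsis plants, 1 array per group, each from a pool of 10 plants. The groups were WS without ABA, WS with ABA, gpa1 without ABA and gpa1 with ABA. ABA is the hormone of drought and seed dormancy, and GPA1 is the alpha subunit of the heterotrimeric G protein. The series title names the question as the comparison of the wild type with a gpa1 mutant in response to ABA. Median intensities were 48.0 for WS control, 43.5 for WS ABA, 47.7 for gpa1 control and 42.8 for gpa1 ABA. Between 28.6% and 30.9% of probe sets on an array lay at or below the floor.

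Arrays of the same treatment resembled each other more than arrays of the same genotype. The correlation of log2 intensities across probe sets was 0.971 between the 2 control arrays and 0.968 between the 2 ABA arrays. It was 0.830 between WS control and WS ABA, and 0.843 between gpa1 control and gpa1 ABA. The arrays were not alike in technical readings. The scanner background was 56.26 for WS control, against 67.04 to 69.51 on the other arrays. The 25S ribosomal RNA probe set read 2236 on WS control, 959 on WS ABA, 1549.8 on gpa1 control and 1800.2 on gpa1 ABA. The geometric mean of the 9 spike-in controls was 687, 395, 456 and 641 in the same order. The ratio of the 3-prime to the 5-prime probe set of actin was 6.09, 8.55, 8.71 and 6.76. The 25S ribosomal RNA, the spike-in controls and the actin ratio set WS control and gpa1 ABA apart from WS ABA and gpa1 control. The difference between the ABA responses of the genotypes contrasts the same pairs of arrays. The same ratios of GAPDH and ubiquitin did not split the arrays this way.

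The gene disrupted in the mutant was not checked here, since the annotation used did not name the probe set of GPA1. The labels give AT3G26300 as the locus of the insertion, which the annotation names CYP71B34, a cytochrome P450 gene. GPA1 is AT2G26300, so the locus and the gene name of the labels differ, and which of them is meant is not given in the sources used here. The intensity of CYP71B34 was 105 in WS control, 122 in WS ABA, 117 in gpa1 control and 105 in gpa1 ABA. The averaged genotype difference was -0.03 on the log2 scale, with a limma adjusted p of 0.993, so no difference of CYP71B34 passed the test. Where its probes lie relative to the insertion is not given in the sources used here, so the value checks neither the label nor the locus. The name gpa1 stands here for the arrays labelled gpa1.

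The first comparison asks which transcripts changed with ABA in both genotypes. ABA raised 4 of the 5 tested markers of the hormone and lowered 4 of the 5 tested members of the cell wall list. XERO2, a dehydrin also called LTI30, rose 38.8-fold in WS and 31.5-fold in gpa1. Its averaged change was 5.13 ± 0.14 (SE) on the log2 scale, with a limma adjusted p of 2.31e-78. PUB19, a U-box ubiquitin ligase, rose 31.2-fold and 28.3-fold, and OCT1, an organic cation transporter, 16.6-fold and 9.41-fold. The remaining named genes with the largest rises were AT2G37870, AT2G41190, AT4G33550, AT1G05340, AT3G57010, AT5G39520 and AT1G73480, with averaged changes from 3.58 to 4.88 on the log2 scale.

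Several transcripts were at the floor on both control arrays and bright after ABA. AT3G02480 rose at least 161-fold in WS and at least 160-fold in gpa1. LEA4-5, a late embryogenesis abundant protein, rose at least 81.1-fold and 103-fold, and SAG29, a sugar transporter of the SWEET family, at least 58.6-fold and 49.5-fold. AT3G17520 and COR15A, a cold-regulated protein of the chloroplast stroma, rose at least 46.9-fold and 30.7-fold in WS and at least 53.5-fold and 32.8-fold in gpa1. In the other direction, TBL45, a trichome birefringence-like protein, fell to the floor on both ABA arrays, at least 21.3-fold in WS and 24.2-fold in gpa1. AT5G63180, AT4G32605, BZIP61 and AT3G01260 also reached the floor with ABA, with falls of at least 3.97-fold to 9.94-fold in WS and 4.26-fold to 10.8-fold in gpa1. All of these passed the limma test, the least of them AT3G01260 with an adjusted p of 3.91e-12.

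Among genes measured on all arrays, AT4G15390 had the lowest averaged change, -3.57, and fell 13.5-fold in WS and 10.5-fold in gpa1. AT4G24780, a pectate lyase family gene, fell 15.3-fold and 8.42-fold. UGT72E1, a glucosyltransferase of monolignol precursors, fell 10.1-fold and 8.49-fold, with an averaged change of -3.21 ± 0.17 (SE) and a limma adjusted p of 6.93e-42. AT1G19960, AT1G73600, AT4G21870, AT1G06830, AT3G22210, AT1G26250 and AT1G66940 followed, with averaged changes from -3.12 to -2.72.

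In all, limma called 2327 probe sets higher and 3507 lower with ABA, 42.7% of those tested, and 5804 of the 5834 had the same sign in both genotypes. Calling on the average of the 2 genotypes itself favours the same sign in both. At least 2-fold on average, 1082 were higher and 807 lower. The median over all tested probe sets was -0.16 on the log2 scale in each genotype, and small changes should be read against it. With median centring the split turned, to 2880 higher and 2299 lower, or 55.6% higher in place of 39.9%. With the treatment fitted alone on all 4 arrays there were 1825 higher and 2396 lower. With 1 array also left out there were 893 higher and 422 lower without WS control, 732 and 435 without WS ABA, 1001 and 522 without gpa1 control, and 776 and 445 without gpa1 ABA. Among the genes of the fixed lists, LHCB4.3 and EXPA18 lost their call already with the treatment fitted alone. With 1 array left out as well, LHCB4.3, EXPA4 and EXPA18 were called in none of the fits, GH3.3 and HSP22.0 only without gpa1 ABA, COR15B not without WS ABA or gpa1 ABA, and IAA29 not without gpa1 ABA.

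The list of ABA-induced markers had 5 tested members, of which 4 rose and none fell, and 4 rose when adjusted over the list alone. XERO2 and COR15A were among the 4. COR47, a dehydrin, rose 5.34-fold in WS and 7.15-fold in gpa1, and COR15B 2.81-fold and 5.31-fold. DI21 did not pass, with log2 changes of 0.44 in WS and -0.30 in gpa1. The list's median change of 2.63, or 2.79 above the median of all genes, exceeded all 10000 random lists.

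The cell wall list had 5 tested members, of which 4 fell and none rose, also when adjusted over the list alone. The 4 were expansins, proteins that loosen the wall. Over all 11 tested expansins, a family defined after the annotation had been seen, 4 rose and 5 fell, with a median of -0.27 at percentile 24.995 of the random lists, and neither direction passed Fisher's exact test (adjusted p of 0.434 and 0.446). EXPA8 fell at least 29.6-fold in WS, where it reached the floor, and 10.3-fold in gpa1. EXPB3 fell 5.96-fold and 5.11-fold, and EXPA15 3.63-fold and 2.58-fold, while EXPA4 had log2 changes of -1.19 and -0.59. EXPB1, named after its value was seen, had an averaged change of -0.27 and an adjusted p of 0.398 with limma. The median of -1.61, or -1.45 relative to all genes, lay below all 10000 random lists.

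Of the auxin list, GH3.3 and GH3.5, enzymes that conjugate auxin to amino acids, rose 4.61-fold and 1.92-fold in WS and 3.40-fold and 2.14-fold in gpa1. IAA29, an auxin response repressor, fell 2.63-fold and 2.52-fold. LBD16 was the fourth tested member, with log2 changes of 0.58 in WS and -0.40 in gpa1. Thus 2 of 4 rose and 1 fell, with the same counts when adjusted over the list alone, and the list's median of 0.56 lay at percentile 96.9 of the random lists.

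Of the 4 tested members of the light-harvesting and Rubisco list, 1 rose and none fell, again also when adjusted over the list alone. LHCB4.3 rose 1.37-fold and 1.34-fold, with a limma adjusted p of 0.0238, which was 0.0706 without the intensity trend. LHCB4.1, LHCB4.2 and RCA, the Rubisco activase, had averaged log2 changes of -0.40, -0.38 and -0.09 and did not pass, though LHCB4.1 and LHCB4.2 did under quantile normalization. The list's median lay at percentile 38.9. Of the 5 tested light-harvesting proteins, a family defined after the annotation had been seen, 1 rose and 2 fell. Their median was -0.40, at percentile 13.55 of the random lists. Among the 3 tested root markers, 1 fell: EXPA18, a root-hair expansin, with -1.27 in WS and -0.02 in gpa1 and a limma adjusted p of 0.00759 (0.0642 without the intensity trend), also when adjusted over the list alone. EXPA7 and BGLU23 had averaged changes of -0.19 and -0.26 and did not pass, though BGLU23 did under quantile normalization, and the list's median lay at percentile 39.2.

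Other lists had 1 or 2 tested members, too few for a median, and their counts were the same when adjusted over the list alone. PRN1, a pirin known to bind GPA1, was the tested member of the G protein list and rose 2.98-fold in WS and 2.31-fold in gpa1. ZAT10, a zinc finger factor of early stress, rose 4.35-fold and 4.17-fold. HSP22.0, a small heat shock protein, rose 4.13-fold and 2.80-fold. GI of the circadian clock, FAMA of guard cells, SAG101 of defence and the housekeeping gene UBC21 had averaged changes of 0.12, -0.43, 0.21 and 0.23 and did not pass, though UBC21 did under median centring. GID1A and GID1B, gibberellin receptors, had -0.12 and 0.09, and DFR and UF3GT of the anthocyanin pathway -0.13 and 0.05, none of them past the test. EEL of the ABA transcription factors, UGT71B6 of ABA catabolism, the cytokinin regulators ARR15 and ARR16, and PDF1.2 of the jasmonate list were too dim to be tested. The lists of PP2C phosphatases, PYR/PYL receptors, ribosomal proteins, brassinosteroid, ethylene, aquaporins, cell cycle, sugar starvation and seed storage had no member that could be used here.

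**Figure D1:**
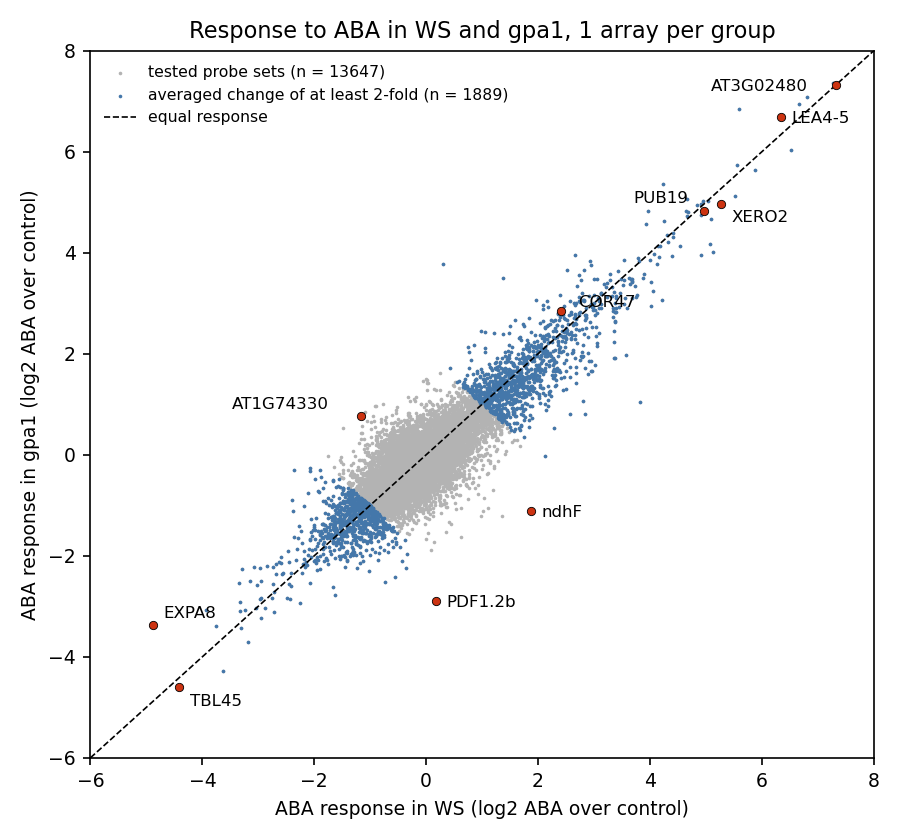
Log2 change with ABA in WS (horizontal axis) and in gpa1 (vertical axis), each point 1 of 13647 tested probe sets and each axis 1 array against 1. Blue points changed at least 2-fold on average (1889 probe sets), the dashed line marks equal responses, red points are named genes, and points against the floor, such as AT3G02480, LEA4-5, TBL45 and EXPA8 in WS, are lower bounds of the change.

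The second comparison asks how the ABA response of each genotype looked by itself and how far the 2 differed. XERO2, PUB19, LEA4-5 and COR47 were higher with ABA in both and TBL45, EXPA8 and UGT72E1 lower in both. The value of ndhF was lower with ABA in gpa1 and higher in WS. PDF1.2b was lower with ABA in gpa1, with a log2 change of only 0.18 in WS. Neither difference was tested. At least 2-fold, 1175 probe sets were higher and 919 lower in WS, and 1070 higher and 939 lower in gpa1. Of these, 886 were higher in both and 519 lower in both. Of the WS changes, 1156 of the 1175 and 897 of the 919 had the same sign in gpa1, and 4 probe sets went opposite ways by 2-fold in each. Under median centring 623 probe sets were lower in gpa1, and with the filter at the 60th percentile 499 were lower in WS, 484 in gpa1 and 302 in both.

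The slope of the gpa1 response on the WS response was 0.975 over the 1889 probe sets with an averaged change of at least 2-fold. By least squares it was 0.937. The probe sets were chosen by the average of the 2 responses, which itself pulls the principal-axis slope towards 1. The slope is therefore weak evidence that the responses were equal. The correlation of the 2 responses across all tested probe sets was 0.864. Among the probe sets higher on average, the median change was 1.71 in WS and 1.56 in gpa1, and among those lower, -1.31 in WS and -1.33 in gpa1. Halved to the scale of the averaged contrasts, the difference of the responses reached 1 for 14 probe sets, against 98 for the genotype difference and 1889 for ABA. The first count was 29 with the floor at the 15th percentile, and with the floor at the 45th percentile the first 2 were 4 and 59. With the filter at the 60th percentile the 3 counts were 1, 46 and 1221. At the smaller size of 0.5 the contrast was less marked. There the halved difference of the responses counted 414 probe sets and the genotype difference 810. No test of the difference of the responses is possible with 1 array per group.

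PDF1.2b, a plant defensin, had an intensity of 300.0 in gpa1 control and 26.5, 30.1 and 40.3 in WS control, WS ABA and gpa1 ABA, so the gpa1 response minus the WS response was -3.08 on the log2 scale. PDF1.2 of the jasmonate list, too dim to be tested, also read highest in gpa1 control, at 62.8, and lay below the floor on the other arrays. ndhF, a chloroplast-encoded subunit of the NDH complex, had 1.88 in WS and -1.12 in gpa1. AT2G20670 and AT1G49500 were higher with ABA in both genotypes, 5.96-fold and 6.98-fold in WS but 1.74-fold and 2.08-fold in gpa1, and both were brighter in gpa1 control than in WS control. AT1G14330, AT2G25730, NET1B, AT3G43590, XPO1B and AT1G21920 had differences from -2.16 to -1.51. In the other direction, AT1G74330, psbN, AT5G55650, AT2G29860, AT2G27790, AT3G06870, AT5G08500, AT4G07990, AT1G55270 and AT5G22580 had differences from 1.60 to 1.94. AT5G22580 was lower with ABA in both, 3.74-fold in WS and 1.23-fold in gpa1. The other 9 were lower with ABA in WS and higher with ABA in gpa1, and so were the spike-in controls and the 25S ribosomal RNA. Choosing genes by the size of this difference itself favours such opposite signs. Of all tested probe sets with a difference of at least 1, 185 had the higher response in gpa1 and 229 the lower.

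By list, the root markers stood out in this contrast. EXPA7 had -0.92 in WS and 0.55 in gpa1, EXPA18 -1.27 and -0.02, and BGLU23 -0.47 and -0.05. The median difference of 1.25 over these 3 genes exceeded all 10000 random lists, and the difference of the responses was not tested. The spike-in controls had a difference of 1.29 and the 25S ribosomal RNA of 1.44. The cell wall list had a median difference of 0.49, at percentile 99.5. EXPA7, EXPA18 and all tested members of the cell wall list are expansins. The 11 tested expansins had a median difference of 0.45, at percentile 99.93. The 11 include the expansins of the 2 lists, so this percentile is no separate support. The 2 list results therefore cannot be read as separate root and cell wall patterns. Whether they share a common pattern was not tested.

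The third comparison asks which transcripts differed in signal between gpa1 and WS whatever the treatment. Genotype and plant stock are the same arrays, so for a single gene their effects cannot be told apart. The signal of ECS1, a cell wall-associated protein, was 33.2-fold lower in gpa1 without ABA and 38.7-fold lower with ABA. Its intensities were 1402 and 1382 in WS and 42.3 and 35.7 in gpa1, and the averaged difference was -5.16 ± 0.15 (SE) on the log2 scale with a limma adjusted p of 4.14e-77. AOP3, an enzyme of glucosinolate side-chain modification, was at the floor on both gpa1 arrays and at least 30.5-fold and 41.2-fold higher in WS. AT4G33720 was 3.94-fold and 6.53-fold lower in gpa1. AT1G73490, 2A6, SBT3.12, a subtilase, AT2G44370, AT5G19240, ZW9, AT5G53150 and ATPMEPCRB, a pectin methylesterase, had averaged differences from -2.05 to -1.32. AT1G23960, AT5G26260, AT2G44200 and AT4G13860 were at or below the floor on both gpa1 arrays and at least 2.18-fold to 5.74-fold higher in WS without ABA.

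Higher in gpa1 were AT5G38020, 3.61-fold without and 5.61-fold with ABA, and AT5G45500, 4.25-fold and 3.33-fold. AT5G37990 was 2.22-fold and 6.01-fold higher. AT5G24210, AT5G23830, AT5G38030, AT5G47050, AT2G16005 and AT5G20700 had averaged differences from 1.11 to 1.62. AT5G54020 was at the floor in WS and at least 3.13-fold and 2.26-fold higher in gpa1. PDF1.2b passed the test with an averaged difference of 1.96, the mean of 3.50 on the control arrays and 0.42 on the ABA arrays. Its call was lost without the intensity trend (limma adjusted p of 0.105) and with robust moderation (0.837), and that of AT5G37990 with robust moderation (0.540). With the floor at the 45th percentile AT5G54020, AT2G44200 and AT4G13860 did not pass. Of the fixed lists, 4 members passed, each also when adjusted over the list alone. EXPA8 was higher in gpa1, with 0.18 without ABA and at least 1.70 with ABA, where WS lay at the floor. DI21, GH3.3 and HSP22.0 had averaged differences of -1.32, -0.79 and -0.86, with limma adjusted p-values of 2.51e-08, 0.000688 and 0.0302. AT5G39520, which rose with ABA, was also lower in gpa1, by an averaged difference of -1.05. Without the intensity trend EXPA8, GH3.3, HSP22.0 and AT5G39520 did not pass (limma adjusted p-values of 0.211, 0.0991, 0.0796 and 0.0833), nor did EXPA8 with robust moderation (0.610) or EXPA8 and HSP22.0 with the floor at the 45th percentile (0.0912 and 0.166).

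Limma called 194 probe sets higher and 202 lower in gpa1, 2.90% of those tested, with 389 of the 396 in the same direction in both treatments. The calls were made on the average of the 2 treatments, which itself favours the same direction in both. The 389 are therefore no separate check of the calls. Without the intensity trend limma called 42 higher and 66 lower. With the genotype fitted alone, on all arrays or with 1 left out, limma called 0, but there the ABA response enters the residual, so those fits do not test the genotype differences. The averaged differences are the same with the genotype fitted alone on all arrays. With 1 array left out, where part of the ABA response enters the difference, 27 of the 34 named genes that were called kept their sign. The 7 that did not were AT5G39520, AT5G22580, AT2G20670, AT1G49500, GH3.3, HSP22.0 and EXPA8, all of which were also called with ABA. AT5G38020 went from 2.17 to between 1.96 and 2.38, and ECS1 from -5.16 to between -5.29 and -5.04. PDF1.2b ranged from 0.51 to 3.41, and ZW9 from -2.67 to -0.003. At least 2-fold without ABA, 82 probe sets were higher and 74 lower, and with ABA 89 were higher and 151 lower, of which 19 were higher and 36 lower in both. With the floor at the 45th percentile there were 47 and 49 without ABA, 54 and 98 with ABA, and 21 lower in both. With the filter at the 60th percentile there were 42 and 29 without ABA, 39 and 60 with ABA, and 12 and 16 in both. The 2 genotype differences correlated at 0.270 across probe sets.

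The called genes were unevenly spread over the 5 chromosomes, with a chi-square statistic of 60.3 and a permutation p of 0.0001, the smallest that 10000 random placements can give. On chromosome 3, 9 of 1433 tested genes were called (0.628%), and on chromosome 1, 29 of 1841 (1.58%). Chromosome 2 had 31 of 1084 (2.86%), chromosome 5 71 of 1743 (4.07%) and chromosome 4 49 of 1042 (4.70%). Of the 10 named genes most above WS in gpa1, 8 lay on chromosome 5. The 10 most below WS were spread otherwise, with 4 on chromosome 1, 1 on chromosome 2, 3 on chromosome 4 and 2 on chromosome 5. Spearman's correlation between the genotype differences without and with ABA, across genes, was 0.0339 on chromosome 3, 0.122 on chromosome 1, 0.138 on chromosome 2, 0.235 on chromosome 5 and 0.248 on chromosome 4. Genes are not independent replicates, so these 5 values describe the arrays.

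**Figure D2:**
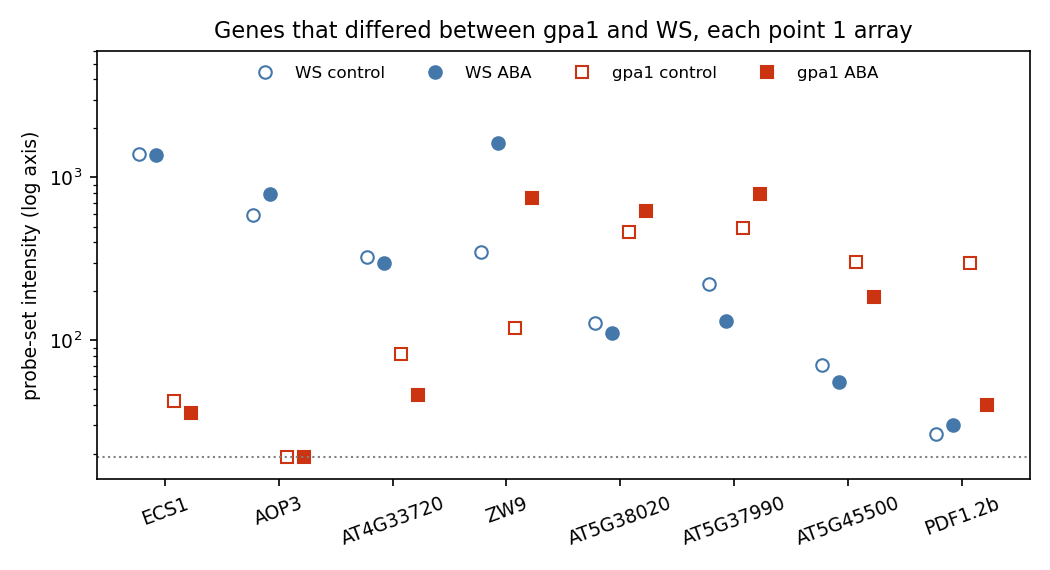
Probe-set intensity on a log axis for 8 genes that differed between gpa1 and WS, each point 1 array (circles WS, squares gpa1, filled with ABA), with the dotted line at the floor of 19.2. ECS1 and AOP3 were lower on both gpa1 arrays, while PDF1.2b was bright on the gpa1 control array alone.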

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

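The test on dim probe sets that goes with the spike-in controls was planned, and the test on the brightness of the largest differences was chosen after the result was seen. The results here are genes named above whose ABA response went 1 way in WS and the opposite way in gpa1, each by more than 0.374 on the log2 scale, the larger SD of the log2 differences between the arrays of 1 treatment. With 1 array per group the difference was not tested for any of them.

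Lower with ABA in WS and higher in gpa1 were AT1G74330, with a gpa1 response minus WS response of 1.94, psbN with 1.93, AT5G55650 with 1.87, AT2G29860 with 1.77, AT2G27790 with 1.74 and AT3G06870 with 1.71. AT5G08500 had a difference of 1.70, AT4G07990 of 1.63, AT1G55270 of 1.60, AT5G24210 of 1.498, EXPA7 of 1.47 and AT5G37990 of 1.43. Higher with ABA in WS and lower in gpa1 were ndhF with -2.998, NET1B with -1.72, AT3G43590 with -1.63, XPO1B with -1.60, AT1G21920 with -1.51 and LBD16 with -0.99.

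Noise of dim probe sets is a candidate explanation for the largest differences of the response. Of the 414 probe sets with a difference of at least 1, 280 (67.6%) lay in the dimmest of 3 equal bins of the tested probe sets and 40 in the brightest bin, and the SD of the difference was 0.533 and 0.338 in these bins. A common offset of dim probe sets that follows the spike-in controls is argued against, since the median difference over the dimmest bin was -0.0220 while the spike-in controls had 1.29. A true difference between the genotypes in single genes stays open and was not tested. It cannot be told apart here from technical differences between the arrays. The actin ratio, the 25S ribosomal RNA and the spike-in controls split the arrays into the same pairs as the difference of the response. The GAPDH and ubiquitin ratios did not.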

How the results depend on the processing

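No alternative was chosen after the result was seen except the unfiltered test without probe sets at the floor on all arrays, which gave 2451 higher and 3828 lower with ABA and 203 and 228 for the genotype. No paired analysis was possible because each group has 1 array, and so no replicate number pairs arrays; the reported fit already compares the treatments within each genotype. Of the values past their test 17 changed sign, all with 1 array left out, where part of the dropped factor enters the difference. The ranges over these fits for the genotype were -3.16 to 1.06 for AT5G39520, -1.77 to 0.13 for AT5G22580, -0.26 to 2.31 for AT2G20670, -0.75 to 2.05 for AT1G49500, -1.89 to 0.31 for GH3.3, -1.88 to 0.17 for HSP22.0 and -1.503 to 3.38 for EXPA8. For ABA they were -3.11 to 0.39 for PDF1.2b, -1.58 to 0.51 for AT5G45500, -0.0365 to 1.297 for AT5G47050, -1.84 to 0.87 for AT4G33720 and -1.59 to 0.0146 for AT2G25730. For the counts of each comparison and the slope, 103 values under the alternatives stayed close to the reported one (counts within 1.5 times) and 39 did not. Of the other values, among them list medians, named genes and counts shared by both genotypes or treatments, 1766 stayed, 86 moved, 349 lost their call and 4 gained one. With no filter, limma called 0 higher and 0 lower for ABA and 0 and 0 for the genotype, with 5054 and 1186 at an unadjusted p under 0.05; that setting adds 5116 probe sets at the floor on all arrays. Leaving out 1 array, where the other factor is also dropped, gave 732 to 1001 higher and 422 to 522 lower with ABA, against 1825 and 2396 with all 4 arrays and the treatment alone. For the genotype these fits gave 0 to 0 higher and lower, and the genotype fitted alone on all arrays 0 higher and 0 lower (120 unadjusted). There the ABA response enters the residual, so these 0s do not test the genotype differences. Limma without trend gave 42 higher and 66 lower, all of them among the calls reported. Median centring gave 2299 lower with ABA and 623 lower by 2-fold in gpa1. With the filter at the 60th percentile, which tests fewer probe sets, 499 were lower by 2-fold with ABA in WS and 484 in gpa1, gpa1 against WS gave 42 higher and 29 lower without ABA and 39 and 60 with ABA, and 1 halved difference of the response reached 1. With the floor at the 45th percentile these were 47 and 49, 54 and 98, and 4, and with the floor at the 15th percentile 29 halved differences. Except where construction shows it, the cause was not tested. Of 56 named genes called with ABA, 45 were called with the treatment alone and 39 to 42 with 1 array also left out. Of 34 called for the genotype, 26 were called without trend and 0 with the genotype alone, for the reason above. Signal near the floor of 19.2 limits dim genes to bounds.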

Other observations

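The tests here of chromosome clustering, spread over chromosomes, scaling and chloroplast transcripts were chosen after the result was seen, and the 2 tests next to the loci of the insertion were planned. Of 33 gene families, 1 passed Fisher's exact test after adjustment. All 5 tested genes of the LEA, dehydrin and COR family rose with ABA, with an adjusted p of 0.00670 and a median log2 change of 3.02. The UDP-glycosyltransferases came next, with 10 of 24 higher and 5 lower, an adjusted p of 0.0763 and a median of 0.26 at percentile 99.93 of random lists. Of 13 serine carboxypeptidase-like proteins 8 fell and 1 rose, with an adjusted p of 0.121 and a median of -0.37 at percentile 8.67. Of 10 autophagy genes 5 rose and none fell, with an adjusted p of 0.167.

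Several families had medians below nearly all random lists without passing Fisher's exact test. Among the tubulins, the subunits of microtubules, 5 of 7 fell, with a median of -0.76 and an adjusted p of 0.167. Of the IQ-domain proteins 6 of 10 fell, with a median of -0.76 and an adjusted p of 0.213, and of the GH9 endoglucanases 4 of 6, with a median of -1.03 and an adjusted p of 0.302. Of the trichome birefringence-like proteins 7 of 15 fell and 2 rose, with a median of -0.60 and an adjusted p of 0.333. The median of all genes was -0.16.

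The genotype difference was uneven along the genome, and a hypothesis is that the gpa1 stock may carry chromosome segments of another background. Of 189 called genes, 79 pairs lay within 10 tested genes of each other, against 49.6 for random placements with an upper bound of 64.0 and a permutation p of 0.0003, while as many genes with the largest ABA response gave 58 pairs (permutation p of 0.1). Part of that excess follows from the uneven shares of the chromosomes: placements shuffled inside each chromosome gave 64.3 pairs on average with an upper bound that the 79 did not pass (permutation p of 0.041), so clustering inside chromosomes stays undecided. The densest windows of 50 tested genes held 5, 6, 2, 7 and 8 called genes on chromosomes 1 to 5, where the densest window of random placements had an upper bound of 7.0. That bound comes from placements over all chromosomes and does not allow for the larger shares of chromosomes 4 and 5. The windows therefore do not decide on clustering inside chromosomes either. Loss of GPA1 acting alike on every chromosome is argued against as the whole cause by the chi-square statistic of 60.3 (random upper bound 10.7; 1.47 for the largest ABA responses). Among the 100 tested genes on either side, 4 were called around AT2G26300 and 1 around AT3G26300. Random placements over all chromosomes gave 5.31 and 5.29 on average, with an upper bound of 10.0. These counts argue against a long segment rich in called genes next to the insertion. A shorter segment with fewer called genes would stay under that bound and remains open. Scaling is argued against by the 92.9% of calls made again under quantile normalization. Effects of GPA1 on single genes stay open, since genotype and stock are the same arrays.

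The chloroplast-encoded genes had a median difference of the response of 0.26, at percentile 99.9 of random lists. The scaling of the arrays is a candidate explanation, since quantile normalization left a median of 0.0316. A larger share of non-messenger RNA on single arrays cannot be told apart from it: 49 of 68 genes (72.1%) had a positive difference, between the bounds set for and against, and the 25S ribosomal RNA had 1.44. A difference between the genotypes was not tested.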
